A study of Danio rerio with 16 samples.

How the data were processed

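Total RNA of 16 samples of zebrafish embryos was hybridized by the authors to 1-colour (Cy3) Agilent miRNA arrays, 4 arrays each of vehicle and VPA embryos at 48 and at 96 hpf. The deposited scanner files give the intensity of each spot, background-subtracted and spatially detrended within the array but not normalized between arrays, made per the file headers with Agilent Feature Extraction 9.5.3.1 (9.5 in the submitters' processing notes) on a GenePix 4000B scanner. The deposited table of values holds the same intensity rounded to 3 digits, with 100% of its values within 1% of the scanner files, and no scaling. Other deposited columns are flags of 0 or 1, per the file headers, for spots well above background, saturated or non-uniform. Per the file headers the array design is annotated on danRer6 (Zv8).

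Each array holds 10360 non-control spots of 548 probes, 518 of them for 245 zebrafish miRNAs and the rest for 14 pufferfish names, with 2 to 4 probes per miRNA and 10 to 20 spots per probe. The 715 control spots and the spots marked as outliers (3.32% to 8.07% per array) were left out. The signal was divided by the 75th percentile over all non-control spots of the array, since 56.0% of probes, over the preset 50%, were detected on an average array. It was then floored at 0.0682, the median over arrays of the lowest scaled signal well above background, which is -3.87 on the log2 scale, and log2 values were averaged over the spots of a probe. The probe with the highest mean stood for each miRNA. A miRNA was tested if most of its spots were well above background on at least 3 of 4 arrays of at least 1 group, which held for 178, and 67 zebrafish miRNAs were not tested. A fold was written as a lower bound where 1 group had 0 arrays well above background, and no fold is given where both groups had 0. The bound was taken against the lowest signal well above background of each array of that group, or the miRNA's own value where higher.

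Group means of the 16 arrays were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with the package data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The contrasts were VPA minus vehicle at 48 and at 96 hpf, the difference of these effects (96 minus 48 hpf), and 96 minus 48 hpf in vehicle and in VPA embryos. Tests were two-sided and p-values were Benjamini-Hochberg adjusted over the 178 miRNAs of a contrast (for pufferfish names, over the 3 detected), with 0.05 as the threshold. The 15 miRNA lists (neuronal, sensory organs, muscle, liver gut and pancreas, cartilage and mesenchyme, epithelium, blood, endothelium, stress and p53, Hox cluster, and the miR-430, miR-17/miR-92, let-7, miR-15/16 and miR-99/miR-100/miR-125 families) were tested with limma's camera at its preset correlation of 0.01 over 4 contrasts, 60 tests adjusted together. The groups, tests, lists, alternatives and the rule for named miRNAs were fixed before the data were examined. The rule took, for each of the first 4 contrasts, up to 12 miRNAs past the threshold with the largest rise and 12 with the largest fall, 2 to 4 members of each list with the largest change, and up to 12 of those that passed in the same direction at both times.

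The arrays lie on 2 slides of 8, with every 48 hpf array on slide 1 and every 96 hpf array on slide 2, so the VPA contrasts are within a slide while age and slide cannot be told apart. Within each slide, column 1 holds vehicle and column 2 VPA arrays, so column and treatment cannot be told apart, and the row follows the replicate number. Whether replicate numbers pair the arrays was checked from the correlation of residuals. At 96 hpf vehicle and VPA arrays of the same number gave r = 0.289, 0.282, 0.276 and 0.248, each the highest for its number and above the threshold of 0.1, and at 48 hpf 0.0971, -0.179, 0.324 and -0.151, so that numbers paired the arrays at 96 hpf only. No label says that replicates are separate clutches, so p-values measure the spread between the arrayed samples. Other probes of the called miRNAs gave the same sign for 47 of 47 at 48 hpf and 44 of 44 at 96 hpf, and probes may share signal between close family members.

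On simulated data for the 48 hpf comparison, with 178 miRNAs of which 40 were changed, 50 runs recovered 66.7% of 14 changes of 0.3, 95.2% of 13 changes of 0.6 and 99.8% of 13 changes of 1 on the log2 scale, with 1.64 false calls on average. The simulated noise was independent between miRNAs and arrays, with no floor, no scaling and no array lying apart. These rates may therefore be better than those in the real data. Relations to development used vehicle arrays split in all 6 ways and 1000 simulations of unchanged groups. At 96 hpf, permutations were also run within pairs of replicate numbers, a choice made after the results were seen. Alternatives tried were normexp background correction (offset 50), other scalings, filters and floors, the mean of all probes, the deposited value table, a trended robust prior, array weights, only the groups compared, replicate and slide blocks, other thresholds, and leaving out each array in turn. A replicate block within each slide, the scanner software's signal per miRNA, and leaving out VPA arrays brighter than every vehicle array of their time were added after seeing the data. Coordinates are those of the array design, as 1-based positions. Pufferfish probes, control spots and saturation flags were not used in the comparisons.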

Results

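MicroRNAs (miRNAs, short RNAs that repress target messenger RNAs) were profiled in wild-type zebrafish embryos of the TL strain that were kept in valproic acid (VPA, an anticonvulsant that inhibits histone deacetylases) or in its ethanol vehicle from 4 hours post-fertilization (hpf). Samples were taken at 48 hpf and at 96 hpf, with 4 arrays for each of the 4 groups and 16 arrays in all, and the labels give no dose. Of 245 zebrafish miRNAs on the array, 178 were detected and tested. The 75th percentile of the signal per array ran from 897 to 1220 in the vehicle group at 48 hpf and from 1956 to 2406 in the vehicle group at 96 hpf. The VPA arrays spread more widely, at 730, 522, 507 and 2356 at 48 hpf and at 1249, 1465, 3415 and 6179 at 96 hpf. Mean log2 brightness did not separate VPA from vehicle (exact two-sided permutation p = 0.486 at 48 hpf and 0.686 at 96 hpf, n = 4 against 4, where the smallest possible p is 0.0286). Within pairs of replicate numbers at 96 hpf p was 0.75, where the smallest is 0.125. Probes well above background averaged 53.2% ± 1.49 (SD, n = 4) in vehicle and 49.3% ± 5.10 in VPA embryos at 48 hpf, and 58.9% ± 2.17 and 62.5% ± 4.87 at 96 hpf. The 4 arrays per group limit the precision of every value.

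**Figure D1:**
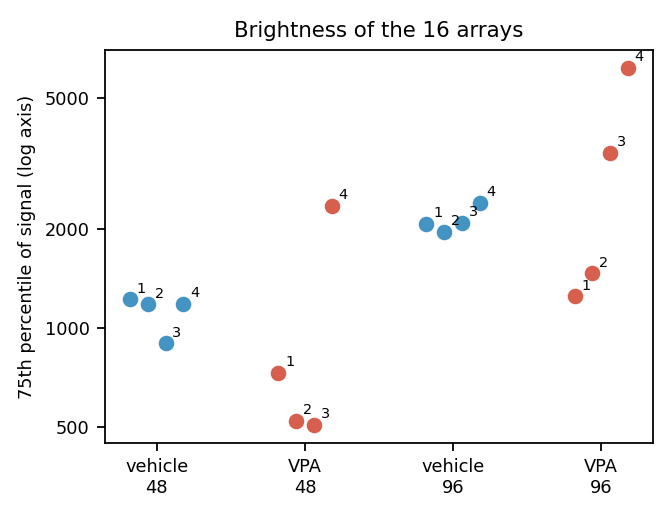
The 75th percentile of the background-subtracted signal of each of the 16 arrays (log axis), by group, with replicate numbers beside the points. The vehicle arrays of each time lie close together, whereas VPA arrays reach from 507 to 2356 at 48 hpf and from 1249 to 6179 at 96 hpf.

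The first comparison asked which miRNAs differ in embryos exposed to VPA at 48 hpf. The miRNAs of the miR-183 cluster, which are expressed in hair cells and photoreceptors, were lower: miR-182 was 1.62-fold lower (log2 change -0.70 ± 0.07, SE, n = 4 arrays a group, adjusted p = 6.51e-06), its opposite arm miR-182* 1.84-fold lower (adjusted p = 6.51e-06) and miR-96 1.66-fold lower (adjusted p = 0.000254). The cluster's miR-183 had a similar change of -0.65 ± 0.25 that did not pass (adjusted p = 0.0666). It did pass without VPA at 48 hpf replicate 2 (-0.79) or VPA at 96 hpf replicate 1 or 4. Normalized log2 intensity of miR-182 was 0.77 ± 0.10 (SD, n = 4) in vehicle and 0.07 ± 0.12 in VPA embryos. The liver miRNA miR-122 was 1.45-fold lower (adjusted p = 0.000106), miR-192 of the gut and liver 1.56-fold lower (adjusted p = 0.000858), and miR-724 1.94-fold lower (adjusted p = 6.28e-07). miR-190b was well above background on all 4 vehicle arrays and on 0 VPA arrays, which makes it at least 1.63-fold lower (adjusted p = 0.000479). Among the miRNAs that were higher, miR-16a rose 1.45-fold (log2 change 0.53 ± 0.08, adjusted p = 0.000254), miR-429 1.27-fold (adjusted p = 0.000212), and miR-457b by 0.33 on the log2 scale (adjusted p = 0.000254).

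In all, 52 of the 178 miRNAs passed at 48 hpf, 29 higher and 23 lower, with a median fold of 1.24 and 1 change of at least 2-fold. That 1 is miR-190b, whose VPA values lie near the floor and whose lower bound is 1.63-fold. All 4 VPA arrays lay on the called side of the vehicle mean for 51 of the 52. VPA and vehicle arrays did not overlap for 74 of all 178 miRNAs, of which 46 were called, where chance would part 2.86%. Leaving out 1 array turned the balance, to 15 higher and 23 lower without vehicle at 48 hpf replicate 3, and to 22 and 24 or 20 and 23 without VPA at 48 hpf replicate 1 or 2. On the array design's genome build (danRer6, Zv8), the probe of miR-182 matches chromosome 4 at 14886082 to 14886098, that of miR-183 at 14884996 to 14885012 and that of miR-96 at 14885149 to 14885169. miR-16a lies on chromosome 15 at 1612512 to 1612528, miR-190b on chromosome 14 at 14775389 to 14775407, and miR-724 on chromosome 11 at 2283201 to 2283216. The balance turned to 12 higher and 32 lower when the 75th percentile was taken over probes detected on all arrays, to 23 and 28 without a floor and to 23 and 26 with the scanner software's own signal. With normexp background correction 4 miRNAs passed, and the changes of miR-724, miR-182*, miR-192 and miR-122, which are well above background on 1, 1, 3 and 2 of the 4 VPA arrays, turned to 0.21, 0.12, 0.14 and 0.31. With the unscaled intensities of the value table limma called 0 miRNAs, and 8 at an unadjusted p under 0.05 (74 in the scaled values). Without VPA at 96 hpf replicate 4, whose values enter the shared estimate of the spread, 83 passed, 48 higher and 35 lower.

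**Figure D2:**
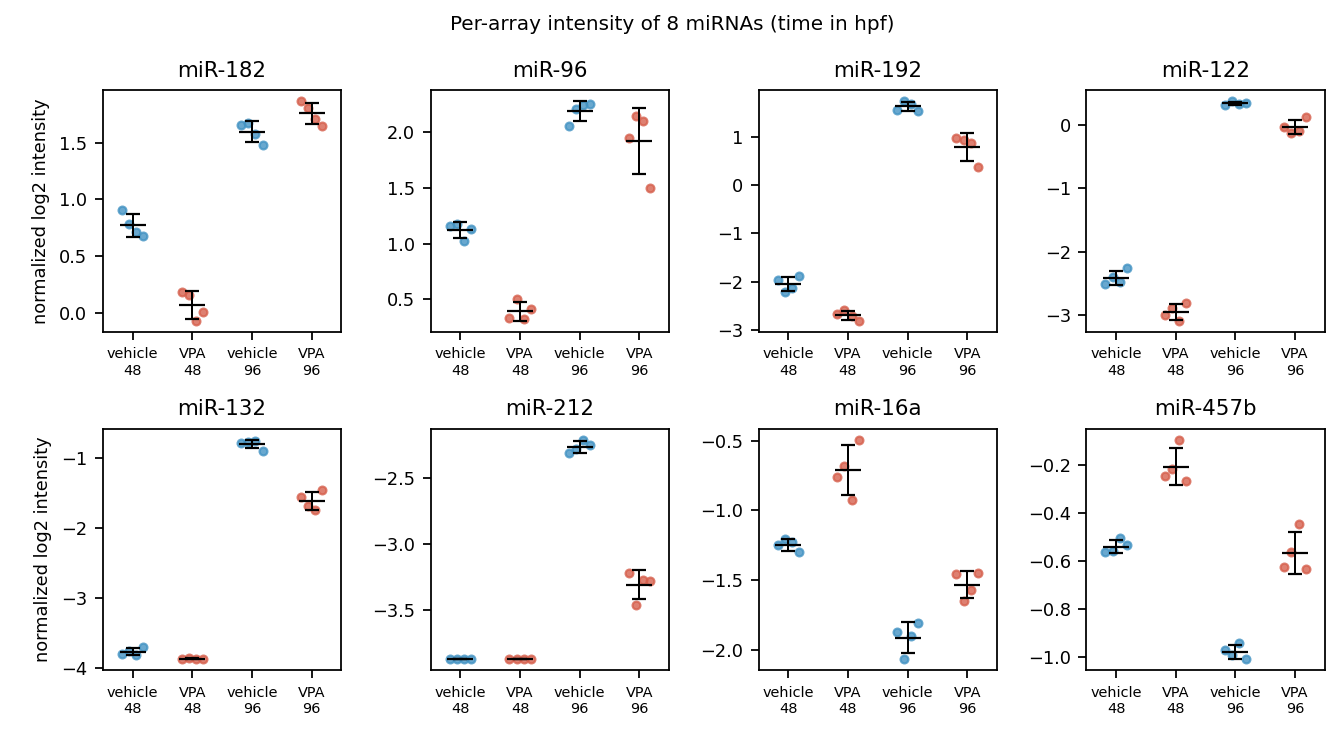
Normalized log2 intensity of 8 miRNAs on each array, in vehicle (blue) and VPA (red) embryos at 48 and 96 hpf, with the mean and SD of the 4 arrays of each group. miR-182 averages 0.77 in vehicle and 0.07 in VPA embryos at 48 hpf and 1.60 and 1.76 at 96 hpf, and miR-212 lies at the floor in both groups at 48 hpf.

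Of 19 measured neuronal miRNAs, 6 were lower at 48 hpf and 0 higher (6 lower also when adjusted over the list alone), among them miR-135c at -0.66, miR-129* at -0.61, miR-138 at -0.60 and miR-218b at -0.48. This list passed (adjusted p = 0.0129), but not as adjusted p = 0.492 with an estimated correlation. In the miR-15/16 family, whose members share a seed sequence, 5 of 7 were higher and 0 lower (5 adjusted over the list alone), with miR-16a, miR-457b at 0.33 and miR-16b at 0.22 (list adjusted p = 0.00795, adjusted p = 0.319 with an estimated correlation), though quantile normalization ended this call and the family's median turned to -0.22 in the unscaled table. The call of miR-15a, among the 5, was lost with the 48 hpf arrays alone, with the mean of all probes and with the 75th percentile over probes detected on all arrays. It was also lost in 3 of the 16 fits that left out 1 array. In the sensory organ list 3 of 6 were lower, and 2 were higher and 4 lower when adjusted over the list alone (list adjusted p = 0.0735). The Hox cluster list had 4 higher and 1 lower of 9 (5 and 1 adjusted over the list alone), with miR-10a at 0.27. The miR-17/miR-92 family, tied to cell proliferation, had 5 higher and 0 lower of 17, with miR-19c at 0.38 and miR-18c at 0.35 (5 and 0 adjusted over the list alone). Of the miR-17/miR-92 family the median was -0.01 where its mean and test pointed up. Of 7 muscle miRNAs 2 were higher, miR-206 at 0.42 and miR-133a* at 0.30 (2 adjusted over the list alone), and the call of miR-206 (adjusted p = 0.0486) was lost in 12 of the 16 fits that left out 1 array. Liver, gut and pancreas miRNAs went both ways, 2 higher and 2 lower of 7, the same counts as adjusted over the list alone. Of 7 cartilage and mesenchyme miRNAs 2 were lower, miR-140 at -0.24 and miR-140* at -0.39, of 10 epithelial ones 2 were higher and 1 lower (3 and 1 adjusted over the list alone), and of 3 endothelial ones miR-126 rose by 0.17. Of 5 in the miR-99/miR-100/miR-125 family, miR-125a fell by 0.61, and of 4 stress and p53 miRNAs, miR-34 fell by 0.36 (0 higher and 2 lower adjusted over the list alone). None of the 5 blood, 4 miR-430 or 8 let-7 miRNAs passed at 48 hpf with all arrays. Of the members followed through the fits that left out 1 array, miR-142a-3p (-0.41), miR-430a (0.17) and miR-430b (0.15) passed without VPA at 96 hpf replicate 4. Without VPA at 48 hpf replicate 4 miR-430c (0.22), let-7a (-0.30) and let-7f (-0.33) passed. Without vehicle at 48 hpf replicate 1 let-7d (-0.30) and let-7f (-0.34) passed. miR-430a also did without vehicle at 48 hpf replicate 4 (0.21) or at 96 hpf replicate 1 or 3.

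The same question was asked at 96 hpf. miR-190b was again lower, 1.99-fold (log2 change -0.99 ± 0.26, adjusted p = 0.00962). Without VPA at 96 hpf replicate 4 its change was -0.62, and its call was lost with the 96 hpf arrays alone. The activity-regulated neuronal miRNAs miR-212 and miR-132, which are processed from a shared transcript, were 2.06-fold (log2 change -1.04 ± 0.05, SE, n = 4 arrays a group, adjusted p = 3.92e-10) and 1.75-fold lower (adjusted p = 6.88e-08) in VPA embryos. miR-29b was 2.11-fold lower (adjusted p = 2.02e-06), the gut and liver pair miR-192 and miR-194a 1.78-fold (adjusted p = 6.01e-05) and 1.77-fold lower (adjusted p = 1.57e-06), and miR-219, a miRNA of oligodendrocytes and brain, 1.76-fold lower (adjusted p = 0.00112). The SE and p-values come from the fit of all 16 arrays. For miR-212 and miR-194a every array of the earlier time lies at the floor of -3.87 and adds no spread. Their SE and p-values thus do not measure the spread of the 96 hpf arrays alone. The blood cell miRNA miR-142a-3p was 1.88-fold lower (adjusted p = 0.000658). The erythroid miRNA miR-451 rose 1.34-fold (adjusted p = 0.000525), miR-455 of cartilage 1.35-fold (adjusted p = 0.000126), and miR-457b 1.33-fold (log2 change 0.41 ± 0.05, adjusted p = 2.51e-05). The blood list's miR-144, whose probe matches chromosome 5 close to that of miR-451, went the other way. Its log2 change of -0.46 did not pass (adjusted p = 0.153). The hypoxia-induced miR-210 rose by 0.39 (adjusted p = 0.0221).

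At 96 hpf 59 miRNAs passed, 26 higher and 33 lower, with a median fold of 1.27 and 2 changes of at least 2-fold. All 4 VPA arrays lay on the called side for 57 of the 59. The groups did not overlap for 57 of all 178 miRNAs, of which 54 were called, where chance would part 2.86%. The split was 14 higher and 29 lower without vehicle at 96 hpf replicate 3, and 17 and 29 without replicate 4 of that group. The probe of miR-212 matches chromosome 15 at 26203892 to 26203907, miR-192 chromosome 10 at 22538377 to 22538394 and miR-194a chromosome 10 at 22538200 to 22538213 on the same build. Because replicate numbers paired the arrays at this time, a fit with the replicate as a block within each slide was added, and it gave 57 miRNAs, 25 higher and 32 lower. The balance turned with some choices, to 34 higher and 25 lower with quantile normalization, 32 and 24 with the scanner software's own signal, 20 and 11 where all 16 arrays had to be well above background, and 18 and 16 without a floor. With normexp background correction limma called 0 miRNAs, and 22 at an unadjusted p under 0.05, and in the unscaled table it called 0 and 0 (76 unadjusted in the scaled values). A fit of the 96 hpf arrays alone gave 36. Without a floor 34 passed, and the calls lost included those of miR-212, miR-132, miR-194a, miR-455, miR-190b, miR-724 and let-7i. Their changes stayed at -1.04, -0.84, -0.83, 0.44, -0.99, -0.66 and -0.47. The SE rose, for miR-212 from 0.05 to 0.60, for let-7i from 0.06 to 0.83 and for miR-724 from 0.08 to 0.25. With the floor, every array of the earlier time lies at -3.87 for miR-212, let-7i and miR-194a and adds no spread to the SE. Normexp turned miR-455 to -0.10, and leaving out the VPA arrays brighter than every vehicle array ended the call of miR-210.

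Of the 19 neuronal miRNAs 8 were lower at 96 hpf and 0 higher (8 adjusted over the list alone), among them miR-212, miR-132, miR-219 and miR-129* at -0.58 (list adjusted p = 0.00131, adjusted p = 0.370 with an estimated correlation). In the miR-15/16 family 6 of 7 were higher and 0 lower (6 adjusted over the list alone), with miR-457b at 0.41, miR-16a at 0.38 and miR-16b at 0.32 (list adjusted p = 0.00131, adjusted p = 0.228 with an estimated correlation). The call of 1 of the 6, miR-457a, was lost with the replicate block within each slide, without a floor and with quantile normalization. Its change of 0.24 was 0.14 without VPA at 96 hpf replicate 4. In the Hox cluster list 4 of 9 were higher and 0 lower (4 adjusted over the list alone), with miR-10a at 0.27, miR-10b at 0.22 and miR-10c at 0.19 (list adjusted p = 0.0217, adjusted p = 0.370 with an estimated correlation). The Hox call was lost with quantile normalization and without VPA at 96 hpf replicate 4, and the list's median turned to -0.07 with normexp. Of 7 liver, gut and pancreas miRNAs 4 were lower, with miR-192, miR-194a and miR-122 at -0.37, and 2 higher, with miR-216b at 0.35 (2 and 4 adjusted over the list alone). Of 4 stress and p53 miRNAs 3 were higher and miR-34 fell by 0.40 (3 and 1 adjusted over the list alone). Of 5 blood miRNAs miR-451 rose and 2 fell, miR-142a-3p and miR-146a (1 and 2 adjusted over the list alone), and the call of miR-146a was lost in 14 of the 16 fits that left out 1 array and with the replicate block within each slide. Of 8 let-7 miRNAs, developmental timing miRNAs, 2 were lower (2 adjusted over the list alone), with let-7i at -0.46, and the family's median of 0.05 lay opposite to its test. Of 17 in the miR-17/miR-92 family 4 were higher (2 adjusted over the list alone), with miR-18c at 0.34. Of 10 epithelial miRNAs 2 were lower, with miR-429b at -0.26, and of 7 cartilage and mesenchyme miRNAs miR-145 fell by 0.43, calls that quantile normalization ended for both of these (to -0.092 and -0.13). The sensory organ list had 1 higher of 6 (0 adjusted over the list alone), miR-184 at 0.22, a call that ended with the replicate block within each slide, without a floor and with the 96 hpf arrays alone, and the miR-99/miR-100/miR-125 family 1 higher of 5, miR-100 at 0.24 (0.15 without VPA at 96 hpf replicate 4). None of the 7 muscle, 3 endothelial or 4 miR-430 miRNAs passed at 96 hpf with all arrays. The brightest probes of miR-206 and miR-133b were saturated on VPA at 96 hpf replicate 4. Without that array the change of miR-206 went from 0.15 to 0.35 and passed, as did miR-430j at -0.24. miR-126* (-0.42) passed without VPA at 96 hpf replicate 3, and miR-430c without vehicle at 96 hpf replicate 2 (-0.27) or VPA at 48 hpf replicate 3 or 4 (-0.22). Lists without a second count kept theirs when adjusted over the list alone at both times.

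The exposure effects at the 2 times were then compared with each other. The effect on miR-182 differed by 0.86 ± 0.10 (SE, adjusted p = 3.87e-05) and that on miR-182* by 0.75 (adjusted p = 0.00078), since at 96 hpf their changes were 0.16 and -0.13 and did not pass. The difference for miR-96 was 0.46 and did not pass (adjusted p = 0.0743), though it did at 0.60 without VPA at 96 hpf replicate 4. miR-210 differed by 0.70 (adjusted p = 0.0105), miR-451 by 0.45 (adjusted p = 0.00983) and miR-21 by -0.67 (adjusted p = 0.00103), being 0.13 at 48 hpf, which did not pass, and -0.54 at 96 hpf. miR-29a differed by -0.54 (adjusted p = 0.00307). miR-212 and miR-194a passed too, but both groups were below background at 48 hpf, so that no fold exists there. In total 22 miRNAs passed, 7 with a higher and 15 with a lower effect at 96 hpf, of which 12 were measured in all 4 groups. The scanner software's own signal gave 15 higher and 8 lower, quantile normalization 10 and 9, and no floor 7 and 4. In the sensory organ list 2 of 6 passed, both higher, or 3 when adjusted over the list alone (list adjusted p = 0.00574, adjusted p = 0.250 with an estimated correlation). Effects were lower at 96 hpf for 2 neuronal, 1 let-7, 1 epithelial, 1 liver, gut and pancreas and 1 cartilage and mesenchyme miRNA (for the last, 2 higher and 2 lower adjusted over the list alone), and higher for 1 blood, 1 Hox cluster and 1 stress and p53 miRNA (2 for the last adjusted over the list alone). The neuronal (miR-212, miR-132), let-7 (let-7i), gut (miR-194a) and cartilage (miR-145) members were below background in 1 or both groups at 48 hpf, so their differences rest on the floor and turned sign without it. No member of the other 6 lists passed, though 2 endothelial miRNAs and 1 of miR-430 were lower when adjusted over the list alone. Without VPA at 96 hpf replicate 4 the count was 43, 20 higher and 23 lower, with normexp 2, where miR-182* turned to -0.45, and with the scanner software's own signal per miRNA the difference of miR-132 turned from -0.71 to 0.97 and still passed.

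Across miRNAs, 22 passed in the same direction at both times and 1, miR-10d*, in opposite directions (-0.19 at 48 hpf and 0.17 at 96 hpf). Among the 12 that were higher at both, against 4.24 for independent lists (Fisher's exact test, one-sided p = 8.22e-05), were miR-16a, miR-457b and miR-18c. The 10 that were lower at both, against 4.26 (Fisher's exact test, one-sided p = 0.00264), included miR-190b, miR-724, miR-192, miR-122, miR-129*, miR-135c, miR-7a, miR-139 and miR-34. Both tests treat the miRNAs as independent, although those higher at both include relatives such as miR-16a, miR-16b and miR-16c. Their p-values may thus be too small. The changes at the 2 times correlated across the 178 miRNAs, which are not independent replicates, with Pearson r = 0.471 and Spearman rho = 0.483.

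**Figure D3:**
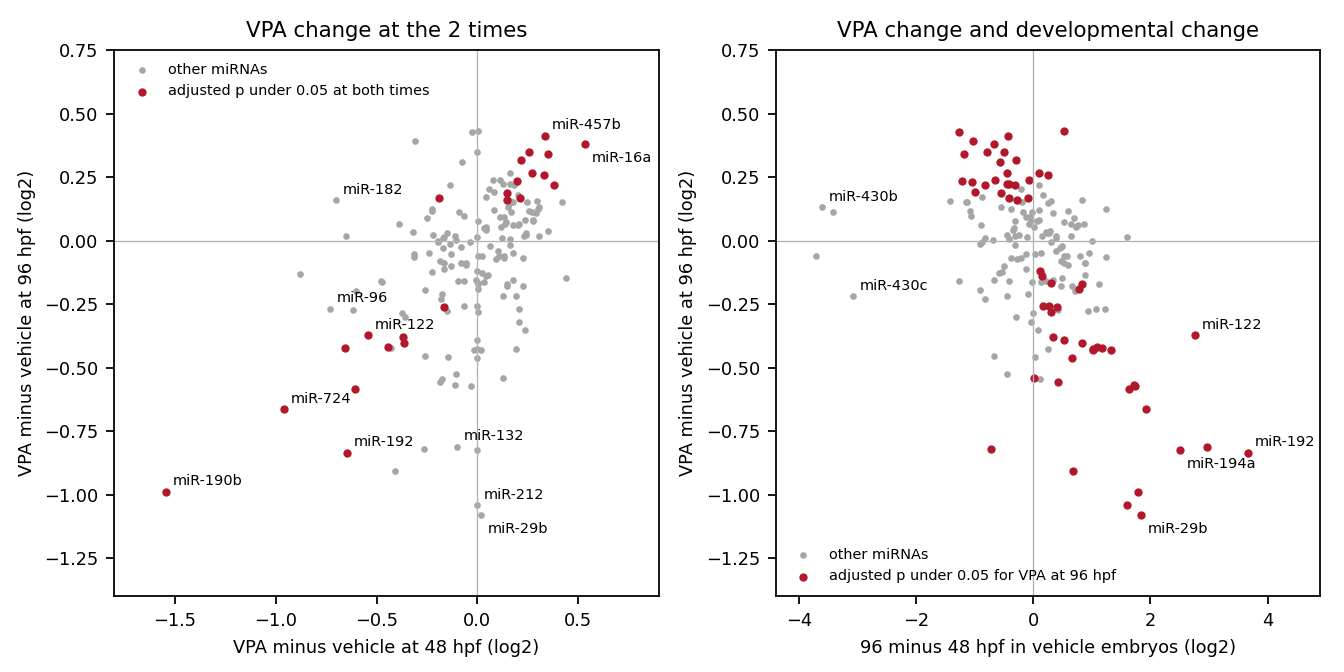
Left, log2 change of each of the 178 miRNAs with VPA at 48 hpf (x) and 96 hpf (y), with those past adjusted p 0.05 at both times in red; right, log2 change between 48 and 96 hpf in vehicle embryos (x) and VPA change at 96 hpf (y), with those past adjusted p 0.05 for VPA at 96 hpf in red. miRNAs low in VPA embryos at 96 hpf, such as miR-192 and miR-29b, are among those that rise most with age.

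Vehicle embryos of the 2 ages were compared to give the scale of normal development. miR-192 rose 12.7-fold from 48 to 96 hpf (log2 change 3.67 ± 0.12, SE, n = 4 arrays a group, adjusted p = 1.24e-13), miR-122 rose 6.76-fold and miR-132 7.83-fold, the last being well above background on 2 of 4 arrays at 48 hpf. The mean of miR-132 in vehicle embryos at 48 hpf was -3.77, near the floor of -3.87, so its fold rests in part on the floor. miR-194a was below background at 48 hpf and at least 4.75-fold higher at 96 hpf, and miR-29b at least 3.04-fold higher. The miR-430 family, which clears maternal messenger RNA in the early embryo, fell steeply, miR-430j 13.1-fold, miR-430b 12.2-fold, miR-430a 10.7-fold and miR-430c 8.41-fold. In all 143 miRNAs passed, 82 higher and 61 lower, 39 of them by at least 2-fold, and in VPA embryos 138 passed, 74 higher and 64 lower. The 39 were counted on floored values and include miR-145 and miR-146a, whose lower bounds were 1.74-fold and 1.72-fold. All 4 of the measured miR-430 miRNAs (list adjusted p = 0.00131, adjusted p = 0.228 with an estimated correlation), all 17 of the miR-17/miR-92 family (list adjusted p = 1.09e-06, adjusted p = 0.212 with an estimated correlation), with miR-92a at -1.27 and miR-363 at -1.21, and all 7 of the miR-15/16 family (list adjusted p = 0.0129, adjusted p = 0.355 with an estimated correlation) were lower. Of 8 let-7 miRNAs 7 were higher, with let-7d at 1.24, and all 7 cartilage and mesenchyme miRNAs were higher, with miR-143 at 1.12 and miR-140 at 0.95 (list adjusted p = 0.0655 for each). Of 9 Hox cluster miRNAs 7 were lower (list adjusted p = 0.0566). The other lists had 10 higher and 3 lower of 19 neuronal, 4 and 1 of 6 sensory organ, 2 and 3 of 7 muscle, 4 and 3 of 7 liver, gut and pancreas, 5 and 3 of 10 epithelial, 2 and 2 of 5 blood, 1 and 1 of 3 endothelial, 2 and 1 of 5 miR-99/miR-100/miR-125 and 1 and 2 of 4 stress and p53 miRNAs. For all 15 lists these counts were unchanged when adjusted over the list alone. Of the 9 list calls in 60 tests, 0 held with an estimated correlation. Each age filled a slide of its own, so age and slide cannot be told apart. The unscaled table shifted the median of all miRNAs to 0.98, against 0.11 in the scaled values, and turned the medians of the miR-15/16 and Hox lists to 0.50 and 0.52, while normexp left 84 miRNAs past the threshold.

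The exposure effect was also set against this developmental change. With the shared vehicle arrays split between the sides, the correlation across miRNAs was -0.385 at 48 hpf and -0.506 at 96 hpf. Without the split it was -0.382 and -0.521, where simulated unchanged groups, also unsplit, gave means of 0.0634 (range -0.189 to 0.294) and -0.0556 (-0.308 to 0.183). The simulated noise was independent between miRNAs, so these ranges do not cover deviations that the miRNAs of an array share. On a scale from the vehicle mean at 48 hpf to that at 96 hpf, VPA arrays lay at -0.114 ± 0.0243 (SD, n = 4) against 0.00383 ± 0.0215 for vehicle at 48 hpf, and at 0.838 ± 0.0273 against 0.997 ± 0.0216 at 96 hpf. The exact two-sided permutation p was 0.0286 at each time, n = 4 against 4, the smallest that permuting 8 arrays freely can give. Replicate numbers paired the arrays at 96 hpf, and within pairs p was 0.125, the smallest that 4 pairs can give, so the position at 96 hpf cannot pass 0.05 that way. Among the 129 miRNAs well above background on all 16 arrays, the correlation at 48 hpf was -0.344, below the lowest of the simulated unchanged groups over the same miRNAs (-0.202, 0 of 1000 as low). At 96 hpf it was -0.258, within the simulated range (-0.316 to 0.210, 17 of 1000 as low). Both correlations had the vehicle arrays split. The simulated means over these miRNAs, 0.0589 at 48 hpf and -0.0611 at 96 hpf, lay near those of the unsplit simulation. The ranges thus appear to be unsplit and not like for like, so the range at 96 hpf cannot decide on the relation there.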

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

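The tests chosen after the result was seen were those of array brightness, probe GC content, place on the slide, miR-430 and falling miRNAs for the developmental position, that of the opposite arm for miR-182, and that of differences between the times with pairs kept; the others were set before. For the count of 52 miRNAs at 48 hpf, 1 of the 35 splits of the 8 arrays gave as many (highest other 1). It was the real split, which is also the split by slide column. The share is under 0.05 and the smallest that 35 splits can give, so chance is unlikely but not excluded. For the 59 at 96 hpf it was 1 of 35 (highest other 5), but replicate numbers pair the arrays there, and the 8 splits that part all 4 pairs are too few for a share under 0.05. Among those 8 the highest other gave 0, while the 27 other splits gave up to 5. For the 143 miRNAs between ages in vehicle embryos 1 of 35 splits gave as many (highest other 0), and for the 138 in VPA embryos 1 of 35 (highest other 9). For the 22 differences between the times 4 of 100 drawn reassignments of treatment, the real one included, gave as many, the highest other being 28, and with treatment swapped only within pairs at 96 hpf 1 of 100 did (highest other 17), a share under 0.05 in both. For the 9 list calls 58 of 100 drawn reassignments of all 16 arrays gave as many (highest other 25). These draws mixed the ages, so the change between ages enters them, and they cannot decide on chance for the 9. For the 5 list calls of VPA, with treatment reassigned within each time, 12 of 100 gave as many (highest other 6), so chance cannot be excluded for these 5.

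VPA embryos lay lower than vehicle embryos on the developmental scale at both times. Array brightness is argued against, since all 8 of 8 VPA arrays, brighter and dimmer than vehicle, had negative slopes on the developmental change, and probe GC content is too, since the slope at 96 hpf stayed at -0.151 (SE 0.00749, n = 4) with GC as a covariate. Slower development of exposed embryos goes with the 52 miRNAs that rise with age (slope -0.210, SE 0.0206). The 56 that fall had a slope of 0.0159 (SE 0.0264). The 4 miR-430 miRNAs among them had a mean change of -0.00840 (SE 0.0785), below the 0.726 that the rising miRNAs predict. These 2 results would argue against a uniform delay if every miRNA changed at a constant rate between the times. No array lies between the times to check that rate, so they cannot decide on a uniform delay. The 2 results are not separate either. Without miR-430 the slope of the 52 that fall was -0.0524 (SE 0.0305), of the other sign, within 2 SE of 0 and still above that of the rising miRNAs. Place on the slide cannot be told apart from treatment (0 vehicle arrays lie in the column of the VPA arrays), so a slower rise of late miRNAs may be a biological candidate, with no second marker of stage tested.

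miR-182, miR-182* and miR-96 were lower at 48 hpf and miR-183 was at -0.65 without passing, a mean over the 4 of -0.739 (SE 0.0815 over 4 arrays), whereas at 96 hpf their mean change was -0.0556 (SE 0.134), or 0.0692 without VPA at 96 hpf replicate 4. Dim VPA arrays are argued against, since the brightest VPA array at 48 hpf had a mean change of -0.923, below the lowest vehicle array at -0.101. The other VPA arrays at 48 hpf, all dimmer than vehicle, had -0.703, -0.536 and -0.796. At 96 hpf the mean change was 0.116 and 0.159 on the dimmer VPA arrays (1249 and 1465). It was -0.0672 and -0.430 on the brighter ones (3415 and 6179). Whether brightness lowers these values was not tested. Binding of related sequences to 1 probe stays open, since the opposite arm miR-182*, at -0.878, was well above background on 1 of the 4 VPA arrays and normexp turned its change to 0.12. Slower development predicts -0.0768 from all miRNAs, or -0.188 from those that rise, if these 4 changed before 48 hpf at the rate seen after it. The mean lay below both, but no array is earlier than 48 hpf, so the prediction cannot decide on slower development. Place on the slide also stays open, and no further biological explanation was tested. The effect at 96 minus that at 48 hpf was 0.86 for miR-182 and 0.75 for miR-182*.

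VPA at 96 hpf replicate 4, the brightest array (6179), lay apart from its group in 14 of the 31 values that stood far from the other 3 arrays of a group, out of 398 tested, where chance gives 19.9. The SD of its deviations over miRNAs was 0.469, against 0.175 to 0.251 on the other arrays. Saturated spots are argued against, since the SD was 0.471 over the 169 miRNAs without one, and a straight trend with probe GC is argued against as the whole cause, since the SD was 0.431 after it was taken out. No biological explanation was tested for 1 array. Its values were miR-138 0.13, miR-218b -0.96, miR-210 0.43, miR-181a* -0.49, miR-142a-3p -3.31, miR-458 -2.89, miR-133c -0.72, miR-34 -0.0072, miR-1 2.06, miR-126b* -0.40, miR-200a 2.02, miR-146a -2.66, miR-19a 0.9996 and miR-153b -1.27 (log2).

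Other arrays far from the rest of their group were these, in log2 intensity. In VPA embryos at 96 hpf replicate 2 had miR-19c at -1.01 and miR-430c at -2.11. In VPA embryos at 48 hpf replicate 4 had miR-92a at 2.09, miR-200a at 2.11, miR-125c at 0.37 and miR-15b at 1.06, replicate 2 miR-129* at -1.18 and replicate 3 let-7d at -2.38. In vehicle embryos at 48 hpf replicate 4 had miR-210* at -1.29 and miR-19a at 2.86, replicate 3 miR-15a at -1.68, replicate 2 miR-133b at 3.77 and replicate 1 miR-10d at -0.33, and the 75th percentile of replicate 3 was 897 against a mean of 1194 for the others. In vehicle embryos at 96 hpf replicate 1 had miR-125a at 0.45, and replicate 2 let-7i at -3.11 and miR-1 at 3.17.

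The exposure effect differed between the times, tested as 96 minus 48 hpf, for 20 further miRNAs. It was lower at 96 hpf for miR-29b at -1.10, miR-212 at -1.04, miR-194a at -0.83, miR-132 at -0.71, miR-21 at -0.67, miR-29a at -0.54, let-7i at -0.46, miR-145 at -0.45, miR-458 at -0.42, miR-459* at -0.39, miR-27c at -0.37, miR-429 at -0.31, miR-221 at -0.30, miR-489 at -0.29 and miR-727 at -0.26. It was higher for miR-103 at 0.35, miR-10d* at 0.36, miR-455 at 0.43, miR-451 at 0.45 and miR-210 at 0.70. For miR-212, miR-194a, let-7i, miR-145, miR-455, miR-459*, miR-489 and miR-727 both groups were below background at 48 hpf, and for miR-29b and miR-132 1 group was, so in these 10 of the 22 the effect at 48 hpf was not measured and the difference is in effect the change at 96 hpf. Without a floor miR-212 turned to 2.32 and let-7i to 1.07. Among probes for pufferfish names, which no comparison used, fru-miR-184 was higher in VPA embryos at 96 hpf by 0.17 (adjusted p = 0.0277 over the 3 detected pufferfish names).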

How the results depend on the processing

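The alternatives chosen after the results were seen were the replicate block within each slide, the scanner software's signal per miRNA and leaving out VPA arrays brighter than every vehicle array. Under 3 other scalings (75th percentile over probes detected on all arrays, quantile, median of those probes) 30 of the 52 calls at 48 hpf and 43 of the 59 at 96 hpf were kept in each, and 28 and 28 when the all-array filter, no floor and the mean of probes were added to make 6 alternatives. Adding normexp left 4 and 0. Normexp raised the median residual SD of the dimmest 45 miRNAs from 0.126 to 0.531. It gave 4 miRNAs at 48 hpf, 0 at 96 hpf, 2 for the difference and 84 between ages in vehicle embryos. The unscaled intensities, in which brightness stays in the values, gave 0, 0, 0 and 78 (limma, with 8, 0, 1 and 91 at an unadjusted p under 0.05, and 49, 22, 49 and 99 for normexp). Array weights, lowest for VPA at 96 hpf replicate 4 at 0.0646, gave 82 at 48 hpf and 55 for the difference, and leaving out bright VPA arrays gave 81 and 50. Requiring all 16 arrays well above background, which tests 129 miRNAs, gave 31 at 96 hpf, 7 for the difference and, for the relation to development, -0.344 at 48 hpf and -0.258 at 96 hpf. Without a floor the counts were 34 at 96 hpf and 11 for the difference. For miR-212, miR-194a, miR-132, miR-135a, miR-190b, miR-145, miR-724 and let-7i at 96 hpf the SE rose while the change stayed or moved little. For miR-194b, miR-489, miR-727 and miR-7b the change moved as well, to -0.69, -0.57, -0.51 and -0.41. For the other calls the cause was not tested. The 96 hpf arrays alone gave 36. A change of at least 2-fold, counted on floored values, left 1, 2, 2, 39 and 37 miRNAs in the 5 contrasts, and an adjusted p under 0.1 gave 37 for the difference. List calls were 0 with an estimated correlation and 30 by fry, which compares a list with no other miRNAs. The other alternatives kept each count within 1.5 times, while the slide block, which is the same split as age, could not change the VPA counts and tests nothing. Leaving out each array gave 38 to 83 at 48 hpf (highest without VPA at 96 hpf replicate 4), 43 to 68 at 96 hpf, 20 to 43 for the difference (highest without the same array), 135 to 151 and 131 to 142 between ages, 8 to 11 list calls, and relations of 0.416 to 0.487, -0.424 to -0.345 and -0.518 to -0.479. These calls were lost most often over the 16 such fits: miR-146a in 14, miR-206 in 12, miR-216b at 48 hpf in 10, miR-27c and, between ages, miR-1 in 7, and miR-140*, miR-30a, miR-184, miR-10d* at 96 hpf and, between ages, miR-99 in 5. miR-126 was lost without vehicle at 48 hpf replicate 3 or VPA at 48 hpf replicate 4, miR-200b without the former, and miR-100 at 96 hpf without vehicle at 96 hpf replicate 3, as was miR-135c, also lost without replicate 4 of that group. Among the named miRNAs, quantile normalization ended the calls of miR-10a, miR-20b, miR-140*, miR-126, miR-216b, miR-206 and miR-429b at 48 hpf, of miR-145, miR-146a, miR-429b, miR-34c, miR-141, let-7e and miR-457a at 96 hpf, of let-7i, miR-145, miR-459*, miR-27c and miR-429 for the difference and of miR-205, miR-429b, miR-142a-3p and miR-99 between ages, and the list calls of miR-15/16 at 48 hpf and Hox at 96 hpf. The replicate block within each slide ended those of miR-216b at 48 hpf of miR-184, miR-146a and miR-457a at 96 hpf and of miR-1, miR-144, miR-126b*, miR-126 and miR-99 between ages. Without VPA at 96 hpf replicate 4 these calls at 96 hpf moved by over 1.5 times: miR-190b to -0.62, miR-181a* to 0.22, miR-34c to 0.15, miR-19d to 0.14, miR-457a to 0.14, miR-100 to 0.15, miR-135c to -0.23 and miR-7a to -0.25. VPA arrays at 48 hpf averaged 49.3% of probes detected, against 53.2% in vehicle, and whether this limits the dim miRNAs was not tested.

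Signs turned for these log2 changes, the cause not being tested except that the unscaled table shifts the median by -0.31 at 48 hpf, 0.20 at 96 hpf and 0.98 between ages. At 48 hpf the unscaled table turned miR-206 to -0.016, miR-19c to -0.057, miR-18c to -0.087, miR-429 to -0.089, miR-457b to -0.10, miR-133a* to -0.13, miR-30a to -0.14, miR-30b to -0.15, miR-216b to -0.18, miR-200b to -0.20, miR-126 to -0.26, miR-20b to -0.19, miR-15a to -0.21, miR-16b to -0.22 and miR-10a to -0.16. Normexp turned miR-724 to 0.21, miR-182* to 0.12, miR-192 to 0.14, miR-122 to 0.31, miR-200b to -0.0022, miR-429b to 0.36, miR-126 to -0.041 and miR-139 to 0.013. At 96 hpf normexp turned miR-455 to -0.10, miR-34c to -0.27 and miR-10d* to -0.25, the unscaled table miR-141 to 0.040 and let-7e to 0.061, and quantile normalization let-7e to 0.079. For the difference between times normexp turned miR-182* to -0.45, miR-455 to -0.85 and miR-10d* to -0.87, and no floor turned miR-212 to 2.32, miR-194a to 1.39, miR-132 to 2.71, let-7i to 1.07, miR-145 to 0.56 and miR-459* to 0.93. The software's signal turned miR-132 to 0.97, and the unscaled table miR-27c to 0.30 and miR-429 to 0.36. Between ages the unscaled table turned miR-184 to 0.61, miR-133a* to 0.39, miR-216b to 0.44, miR-205 to 0.35, miR-144 to 0.27, miR-126b* to 0.65, miR-16a to 0.27, miR-457a to 0.28, miR-457b to 0.50, miR-10c to 0.39, miR-10a to 0.49, miR-10b to 0.52, miR-10a* to 0.11, miR-99 to 0.72 and miR-210* to 0.36, and normexp miR-10a* to 0.019.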

Other observations

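The values in this part were chosen after the results were seen. Of 14 pufferfish miRNA names on the array, 3 passed the same detection filter, fru-miR-184, fru-miR-458 and fru-miR-7, and their p-values were adjusted over these 3. In VPA embryos fru-miR-458 changed by -0.31 (SE 0.05, adjusted p = 0.0001) and fru-miR-7 by -0.46 (SE 0.12, adjusted p = 0.00278) at 96 hpf. The zebrafish probes gave -0.43 for miR-458 and -0.42 for miR-7a at 96 hpf, the latter -0.25 without VPA at 96 hpf replicate 4 and not called with the 96 hpf arrays alone. At 48 hpf the changes of fru-miR-458 and fru-miR-7 were 0.01 and -0.17 and did not pass (adjusted p = 0.925 and 0.285), whereas miR-7a did pass there (-0.44, adjusted p = 0.0135 over the 178 miRNAs).

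In the genome assembly of the gene table (GRCz12tu), used for neighbours only, the genes of miR-182, miR-183 and miR-96 lie on the same chromosome within 1167 bases, and those of miR-192 and miR-194a within 265 bases. The genes of miR-212 and miR-132 form a pair at 2 places, within 354 and 430 bases. When the developmental position of each VPA array was subtracted, 54 miRNAs passed at 48 hpf, 34 of them among the 52, and 45 at 96 hpf, 34 of them among the 59.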
